A study of Homo sapiens with 12 samples.

How the data were processed

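Total RNA of Jurkat cells, a human T cell leukaemia line that grows in suspension, was labelled with Cy5 and measured on 1-colour expression arrays, per the labels. The titles give 4 groups of 3 samples: control and exposed cells at 30 min and at 60 min. The series text instead speaks of a time before exposure, 30 min and 60 min. The titles were followed, and whether controls were collected before exposure is open. Exposed cells had received 2 pulses of 10 ns each at a field of 280 kV/cm, that is, a nanosecond pulsed electric field. No label says whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

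The deposited values are linear spot intensities, 1 column for each of the 12 samples and 54548 probes. The scanner, the background correction and the scaling used by the authors are not given in the sources used here. In the columns labelled 30 min the median was between 0.999 and 1.00 on every array, and 319 to 453 probes per array had values below 0, so the deposited intensities were read as background-subtracted and divided by each array's median; both steps are inferred from the values. The highest value of an array was between 634 and 811 on this scale. All 12 columns were assigned to a sample.

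The columns were compared with each other before any test. Each column labelled 60 min equalled the column labelled 30 min of the same group and replicate number, after values below 0 were set to 0 and 0.08 was added, on all 54548 probes in each of the 6 pairs (tolerance 0.0005). In the 30 other pairs of a 30 min and a 60 min column, at most 163 probes matched in this way. The deposited table was therefore taken to hold 6 measured arrays, 3 control and 3 exposed, each counted once. To which collection time they belong cannot be told from the sources used here. The columns labelled 30 min were used because they are the ones without the added constant. The fit planned before the data were examined shared 1 estimate of the spread over 12 arrays; it was replaced by a fit of the 6 arrays. The comparison at 60 min, the mean effect over both times, the difference between the times, the control and exposed changes over time and the agreement between times were planned and were not computed, since no second measurement was at hand for them.

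From the deposited intensities, log2 values were computed here after values below 0.126 (the percentile 10 of all positive values) had been set to that floor. No further scaling was applied, as the column medians lay close together. The third of probes with the lowest mean, at a level below 0.366, was left out, and 36365 probes were tested. Exposed and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment over the 36365 probes and a threshold of 0.05. Folds are 2 to the power of the mean log2 difference, and understate changes of probes whose control or exposed values lie at the floor. Quantile normalization in place of the deposited scaling was chosen as an alternative before the data were examined; its values stand beside those of the deposited scaling, because it changed the balance of higher and lower calls.

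Probes were named through a probe-to-gene table of the platform. It lists 24225 of the 54548 probes, of which 23328 have a single gene and 897 have several. The other 30323 probes are unnamed here. Updating symbols through gene identifiers changed 0 names. Of the tested probes 17799 had a single gene, for 14500 genes, and the probe of highest mean level stands for its gene in counts of genes and in gene lists. No genome build is named in the sources used here, so no coordinates are given.

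The rule for named genes, fixed before the data were examined, took 10 genes higher and 10 lower in exposed arrays with the largest log2 change among those past the threshold whose 3 exposed arrays all lay on one side of the 3 control arrays. It also took the 4 members with the smallest p in each list of 12 or more measured genes that had a called member, and 2 in other lists. Genes named beyond the rule are members of the fixed lists or, in the closing observations, of gene families that were defined later; they were chosen after their values were seen.

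Fixed before the data were examined were 23 gene lists: immediate early genes, the heat shock response, the unfolded protein and integrated stress response, calcium and NFAT targets of T cell activation, NF-kappaB targets, apoptosis regulators, p53 targets, oxidative stress and metallothioneins, membrane repair and membrane lipid enzymes, calcium stores, pumps and ion channels, actin and tubulin cytoskeleton, cholesterol synthesis, glycolysis and hypoxia targets, mitotic cell cycle, DNA replication, cytosolic ribosomal proteins, the mitochondrial respiratory chain, short-lived transcripts, T cell lineage, B cell, myeloid and erythroid, and epithelial and fibroblast markers, and housekeeping controls. They hold 559 symbols, of which 470 had a probe and 426 were tested. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes, adjusted over the 23 lists. Camera with a correlation estimated per list and limma's fry, which asks whether a list moves on balance one way, were alternatives. With the estimated setting p rose even where the estimate lay below the preset. A call lost with it therefore does not by itself show that the members varied together. Each list's median was also set against 10000 random lists of genes drawn from the same of 50 level bins. The genes of a random list were drawn independently, so the range is too narrow for a list whose members vary together.

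The alternatives tried were quantile normalization, median scaling, a pseudocount of 0.249 (the percentile 25 of positive values) in place of the floor, no filter on dim probes, a stricter filter on dim probes, eBayes without the trend or robust, array weights, the replicate number as a block, and leaving out each array in turn. Chosen after seeing the data were the columns labelled 60 min, the mean of both column sets, all 12 columns as if separate, and cyclic loess. The steps were tested on simulated data: on 36365 probes of 6 arrays with the spread of the real ones, a log2 change of 0.5 was called for 45 of 100 changed probes and a change of 1 for 87 of 100, with 6 false calls, and data without a change gave 0 calls. Of 200 random lists in such data, 8 had an unadjusted camera p under 0.05. The simulated probes varied independently and had no shift that depends on level. These checks therefore do not show how the tests behave where genes vary together, as in the real lists. With 3 arrays against 3 an exact permutation test cannot give a 2-sided p below 0.1, so single probes are called through the spread that limma pools over probes, and the number of arrays limits the precision of every value.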

Results

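Gene expression was measured in Jurkat cells, a human T cell leukaemia line, after exposure to a nanosecond pulsed electric field (2 pulses of 10 ns at 280 kV/cm) and in unexposed control cells. The titles name 12 samples in 4 groups of 3, at 30 min and 60 min. The 6 columns labelled 60 min held the values of the 6 columns labelled 30 min, with values below 0 set to 0, plus a constant of 0.08, on all 54548 probes (tolerance 0.0005), and were not counted again. The results therefore rest on 3 control and 3 exposed arrays, and the collection time of these arrays is open. Levels are deposited intensities, with an array median near 1. Over the tested probes, log2 levels correlated at 0.988 to 0.991 between control arrays, 0.992 to 0.994 between exposed arrays and 0.982 to 0.987 between the groups; probes are not independent replicates.

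The comparison of exposed with control cells asks which transcripts differ after the field. FOS, a subunit of the transcription factor AP-1 and a classical immediate early gene, rose from a level of 3.56 ± 0.311 (SD, n = 3) to 15.9 ± 0.349, which is 4.47-fold (log2 change 2.16, SE 0.077, limma adjusted p = 3.9e-09). KLF4, a zinc finger transcription factor, rose from 1.45 to 3.06, DUSP1, a MAP kinase phosphatase, from 1.48 to 2.70, and CD69, an early activation marker of lymphocytes, from 18.1 to 28.1. Genes of mitosis and DNA replication fell: 20 of 24 measured mitotic genes and 19 of 25 replication genes passed the test as lower and 0 as higher, while after quantile normalization 11 and 12 were lower and 1, the mitotic kinase gene PLK1, was higher. Larger falls were found for TGFBR1, a TGF-beta receptor, NFIL3, a leucine zipper transcription factor, and CD226, an activating receptor of lymphocytes. With BH adjustment over all probes, limma called 6389 of 14500 genes, 1037 higher and 5352 lower in exposed arrays, and after quantile normalization 5007 genes, 1809 higher and 3198 lower.

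**Figure D1:**
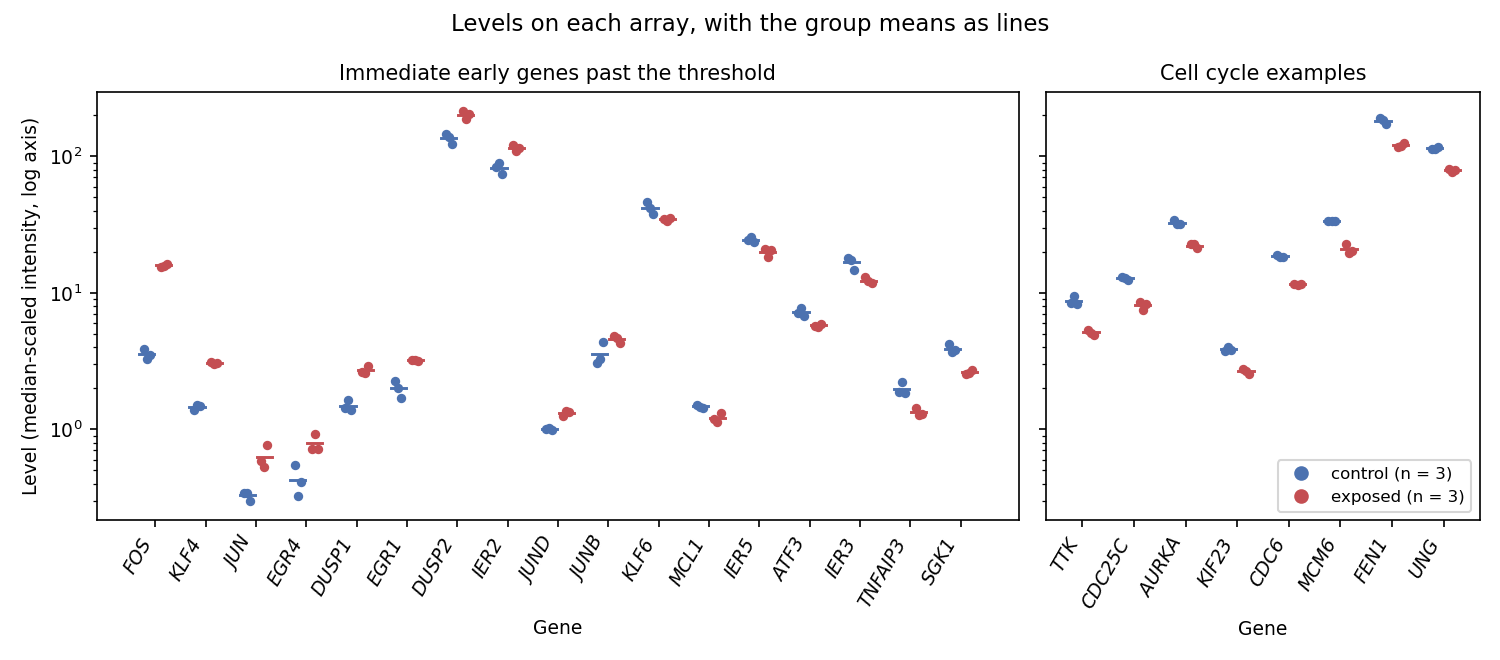
Level of each gene on each array (median-scaled intensity, log axis), for the 17 immediate early genes past the threshold (left) and 8 cell cycle genes (right), with points for the 3 control and 3 exposed arrays and lines for group means. FOS lies between 3.29 and 3.90 on control arrays and between 15.6 and 16.3 on exposed arrays; the falls of IER5 and KLF6 did not pass the test after quantile normalization.

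Besides FOS and KLF4, the 10 largest rises included LINC01829, a long intergenic noncoding RNA, at 1.19 ± 0.137 in control and 2.53 ± 0.211 in exposed arrays (2.12-fold, limma adjusted p = 7.2e-06). The others, DEFB134, ANP32D, OSBPL8, SRGAP3-AS2, SLCO6A1, NSG2 and OOSP2, had control levels between 0.227 and 0.363 and exposed levels below 1, and no fold is given for them: a control array of DEFB134, OSBPL8 and SRGAP3-AS2 lay under the floor of 0.126, and the size and rank of these rises depend on the floor. With the pseudocount the log2 change was 1.10 for DEFB134, 0.91 for ANP32D, 0.85 for OSBPL8, 0.67 for SLCO6A1 and NSG2 and 0.71 for OOSP2, each past the threshold. No value with the pseudocount is given here for SRGAP3-AS2. Of the 10 largest falls, 6 were of genes at higher levels. RINL fell from 16.4 ± 1.97 to 5.96 ± 0.370 (log2 change -1.46, limma adjusted p = 2.7e-07), and TGFBR1 from 4.36 ± 0.438 to 1.58 ± 0.0699 (log2 change -1.46). NFIL3 fell from 3.82 to 1.75, URGCP from 8.25 to 3.86 and CD226 from 3.23 to 1.55. UBAC2 fell from 24.4 ± 1.96 to 12.5 ± 7.11, but the change was -0.56 without exposed array 1, and the call was lost without control array 2 (adjusted p = 0.059) and after quantile normalization (adjusted p = 0.058), with adjusted p between 0.053 and 0.238 under the alternatives that ended it. LOC145474, KLLN, MGP and OTUD7B fell from control levels between 0.592 and 0.789 to between 0.255 and 0.324, also close to the floor. The other tested probe of TGFBR1 had a log2 change of -0.13 (SE 0.17, limma adjusted p = 0.59).

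Several calls at levels below 1 were lost with an array fewer, mostly with a log2 change about as large. Among the rises, limma's adjusted p lay above 0.05 for SLCO6A1 without control array 1 (0.055) or any of the 3 exposed arrays (0.097, 0.136 and 0.086), and for SRGAP3-AS2 without any of the exposed arrays (0.130, 0.071 and 0.094). The same held for NSG2 without any exposed array (0.052, 0.078 and 0.089), for OSBPL8 without exposed array 1 or 3 (0.061 and 0.089), and for OOSP2 without exposed array 2 (0.051). In these fits the log2 change was 1.10 to 1.21 for SLCO6A1 without an exposed array, 1.16 to 1.35 for SRGAP3-AS2, 1.05 to 1.18 for NSG2, 1.22 to 1.41 for OSBPL8 and 1.01 for OOSP2. Among the falls, it lay above 0.05 for KLLN without control array 2 (0.062), for MGP without control array 1 or 2 (0.051 and 0.062) or exposed array 2 (0.055), and for OTUD7B without control array 1 (0.052), with log2 changes of -1.32 for KLLN, -1.05 to -1.20 for MGP and -0.97 for OTUD7B. The log2 change moved by over 1.5 times for OSBPL8 without control array 3 (0.73), SRGAP3-AS2 without control array 3 (0.79), SLCO6A1 without control array 1 (0.74) and KLLN without exposed array 3 (-0.88). Without the filter on dim probes, OSBPL8, SRGAP3-AS2, SLCO6A1 and UBAC2 did not pass (adjusted p between 0.070 and 0.138), nor did OSBPL8 without the intensity trend (0.089) or with the robust fit (0.069), or SRGAP3-AS2 with array weights (log2 change 0.70, adjusted p = 0.058).

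Of the 28 measured immediate early genes, which respond to a stimulus without new protein synthesis, 10 rose, 7 fell and 11 did not pass, and adjusted over the list alone the counts were again 10 and 7. Besides FOS, KLF4 and DUSP1, the genes that rose were EGR1 (1.99 to 3.21), DUSP2 (136 to 202), IER2 (82.5 to 116), JUNB (3.57 to 4.59), JUND (1.01 to 1.32), JUN (0.329 to 0.627) and EGR4 (0.428 to 0.788). Those that fell were SGK1 (3.90 to 2.62), TNFAIP3 (1.98 to 1.33), IER3 (16.7 to 12.3), ATF3 (7.19 to 5.77), MCL1 (1.47 to 1.21), and IER5 and KLF6, whose falls were lost after quantile normalization (adjusted p = 0.55 and 0.91). After quantile normalization 13 were higher, with NR4A2, NR4A3 and ZFP36 added, and 5 lower. FOSB (1.35 and 1.52, adjusted p = 0.21) and NR4A1 (1.83 and 1.87, adjusted p = 0.83) did not pass limma's test. The list stood higher than other genes by camera (adjusted p = 0.0010, and 0.019 after quantile normalization), with a median log2 change of 0.06 and of 0.17 after quantile normalization. The call was lost with a correlation estimated for the list: adjusted p = 0.79 with an estimated correlation, and 0.39 after quantile normalization. The estimate was 0.10 as deposited but -0.003 after quantile normalization, below the preset 0.01. A higher correlation therefore did not cause the loss there, where camera's unadjusted p was 0.00082 at the preset and 0.020 with the estimate.

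Of 13 calcium and NFAT targets of T cell activation, 1 rose and 2 fell, the same numbers adjusted over the list alone. The median log2 change was 0.02 and the mean -0.09, and camera pointed up (adjusted p = 0.33). CD69 rose 1.55-fold from 18.1 ± 0.324 to 28.1 ± 0.132 (limma adjusted p = 1.8e-05). RCAN1, an inhibitor of calcineurin, fell from 14.0 to 8.18, and NFATC1, a transcription factor that calcineurin activates, from 15.7 to 10.6. IL13 had levels of 0.515 and 0.296 and did not pass (adjusted p = 0.053), but passed after quantile normalization (0.047), with the pseudocount (0.039), without the filter on dim probes (0.031), without the intensity trend (0.0074) and with array weights (0.0089), and not on leaving out any array (0.052 to 0.140). Of 16 NF-kappaB targets 1 rose and 8 fell, or 1 and 9 adjusted over the list alone, and after quantile normalization 1 was higher and 7 lower (camera adjusted p = 0.54 and 0.44). LTB, lymphotoxin beta, rose from 3.21 to 3.89. TRAF1 fell from 1.84 to 1.16, NFKBIA, an inhibitor of NF-kappaB, from 7.12 to 5.07, and NFKB1 from 35.2 to 26.1. Of 21 short-lived transcripts and RNA decay genes 3 rose and 4 fell, also adjusted over the list alone; the median and mean log2 change, -0.11 and -0.07, and camera's direction, up, differed in sign (adjusted p = 0.56), and after quantile normalization the median was 0.002. ID3, an inhibitor of helix-loop-helix transcription factors, rose from 18.6 to 24.0 and TOB2 from 0.724 to 1.07, while CXCR4, a chemokine receptor, fell from 78.2 to 54.8 and CNOT1, the scaffold of a deadenylase complex, from 14.1 to 10.6.

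The mitotic list was lower by camera (adjusted p = 0.00044, median log2 change -0.42), a call lost with a correlation estimated for the list (adjusted p = 0.79 with an estimated correlation), and 20 of its 24 genes fell, or 22 adjusted over the list alone. TTK, a kinase of the spindle checkpoint, fell 1.69-fold from 8.69 ± 0.652 to 5.12 ± 0.200 (limma adjusted p = 1.3e-05). CDC25C, a phosphatase that activates CDK1, fell from 12.8 to 8.12, AURKA, a kinase of the centrosome, from 32.6 to 22.2, and KIF23, a kinesin of cytokinesis, from 3.87 to 2.66. The DNA replication list was lower as well (camera adjusted p = 0.00051, median log2 change -0.40), a call lost in the same way (adjusted p = 0.79 with an estimated correlation), with 19 of 25 genes down, also adjusted over the list alone. CDC6, which licenses replication origins, fell 1.59-fold from 18.5 ± 0.384 to 11.6 ± 0.0998 (limma adjusted p = 1.3e-05). MCM6, a subunit of the replicative helicase, fell from 33.5 to 20.8, FEN1, a flap endonuclease, from 183 to 121, and UNG, a uracil glycosylase, from 115 to 78.9. All 8 of these genes also fell after quantile normalization, by log2 changes between -0.25 and -0.63. There the medians of the mitotic and replication lists were both -0.14, and both had a camera adjusted p = 0.038, against adjusted p = 0.39 with an estimated correlation. The deposited medians lay at the percentiles 0.13 and 0.2 of random lists of the same level.

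Of 16 heat shock genes 12 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.033, median log2 change -0.30). The call was lost with a correlation estimated for the list (adjusted p = 0.79 with an estimated correlation). HSP90AB1, a cytosolic chaperone, fell 1.83-fold from 122 ± 10.7 to 66.2 ± 0.717 (limma adjusted p = 4.4e-06), STIP1, a co-chaperone, fell from 40.9 to 27.4 and BAG3 from 13.7 to 9.56. DNAJA1 fell from 127 to 92.0, a call lost after quantile normalization (adjusted p = 0.059). The inducible HSPA1A was at 0.969 and 0.825 (adjusted p = 0.24). The median lay inside the range of random lists of the same level (percentile 16.4). After quantile normalization 5 heat shock genes were lower and the list did not pass (camera adjusted p = 0.15). It did not pass without exposed array 1 either (adjusted p = 0.051).

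Of 22 genes of the unfolded protein and integrated stress response 2 rose and 6 fell, or 2 and 8 adjusted over the list alone. PPP1R15A, a phosphatase subunit that reverses the phosphorylation of eIF2alpha, rose from 1.74 to 2.80 and the co-chaperone DNAJC3 from 7.19 to 9.88. PDIA4, a disulfide isomerase, fell from 9.76 to 5.40, ASNS, asparagine synthetase, from 19.1 to 11.9, and XBP1, a transcription factor of the unfolded protein response, from 39.1 to 27.3. DDIT3 was at 7.86 and 7.84 (adjusted p = 1.00). This list's median was -0.12 and its mean -0.09 while camera pointed up (adjusted p = 0.58), and after quantile normalization the median was 0.08, with 3 genes higher and 4 lower.

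Of 29 apoptosis regulators 15 fell and 0 rose, or 16 and 0 adjusted over the list alone, but after quantile normalization 6 were lower and 4, APAF1, CYCS, BIK and PMAIP1, higher (camera adjusted p = 0.36 and 0.56). The death receptor genes TNFRSF10B (8.09 to 4.73) and FAS (9.66 to 6.09) and the caspase genes CASP9 (15.2 to 9.62) and CASP6 (16.5 to 10.9) fell under both scalings. Of 20 p53 targets and DNA damage response genes 9 fell and 0 rose, or 11 and 0 adjusted over the list alone, and after quantile normalization 8 were lower and 1, PMAIP1, higher (camera adjusted p = 0.23 and 0.18). CCNG1, cyclin G, fell from 18.4 to 14.0 and GADD45B from 9.27 to 7.11. CDKN1A, a cell cycle inhibitor induced by p53, was at 2.43 and 2.43 (limma adjusted p = 0.97). Of 17 genes of oxidative stress and metallothioneins 9 fell and 0 rose, or 10 and 0 adjusted over the list alone, with 2 lower and 2, GPX1 and TXN, higher after quantile normalization (camera adjusted p = 0.42 and 0.99). SLC30A1, a zinc exporter, fell from 10.6 to 7.70 and GSR, glutathione reductase, fell from 33.1 by a log2 change of -0.40. The falls of SOD2 (19.3 to 15.4) and SOD1 (494 to 400) were lost after quantile normalization, that of SOD1 also without the filter on dim probes (adjusted p = 0.15), and SOD1 turned to a log2 change of 0.10 under cyclic loess.

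Of 25 genes of membrane repair and membrane lipid enzymes 14 fell and 0 rose, or 15 and 0 adjusted over the list alone (camera adjusted p = 0.044, median log2 change -0.28). The call was lost with a correlation estimated for the list (adjusted p = 0.79 with an estimated correlation). ANXA11, an annexin, fell from 22.6 to 15.2, VPS4B, an ATPase of the ESCRT machinery, from 80.4 to 59.0, and CAPN1, a calpain, from 1.38 to 0.976. CHMP2A, an ESCRT-III subunit, fell from 111 to 85.7, a call lost after quantile normalization (adjusted p = 0.37). The median lay inside the range of random lists of the same level (percentile 9.24). After quantile normalization 7 genes were lower and 1, the calpain subunit gene CAPNS1, higher, and the list did not pass (camera adjusted p = 0.18). It also did not pass without control array 1 (adjusted p = 0.116) or 2 (0.065), or without exposed array 1 (0.098) or 2 (0.058).

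Of 31 genes of calcium stores, pumps and ion channels 12 fell and 0 rose, also adjusted over the list alone, and after quantile normalization 6 were lower and 1, VDAC2, higher (camera adjusted p = 0.28 and 0.50). TRPV2, a cation channel, fell from 6.59 to 3.84, ITPR3, a calcium release channel of the endoplasmic reticulum, from 3.37 to 2.08, SLC8B1, a mitochondrial sodium-calcium exchanger, from 28.8 to 19.7 and VDAC1, a channel of the outer mitochondrial membrane, from 82.6 to 58.2. Of 14 genes of cholesterol synthesis and uptake 8 fell and 0 rose, also adjusted over the list alone, with 3 lower and 1, PMVK, higher after quantile normalization (camera adjusted p = 0.23 and 0.66). IDI1 fell from 98.6 to 66.5, SQLE from 22.7 to 16.3 and HMGCS1 from 9.69 to 7.03, all enzymes of the pathway, and STARD4 fell from 35.6 to 28.3, a call lost after quantile normalization (adjusted p = 0.42).

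Of 22 actin and tubulin cytoskeleton genes 4 rose and 7 fell, or 5 and 7 adjusted over the list alone, and after quantile normalization 11 were higher and 6 lower. CFL1, cofilin, rose from 229 to 280, RDX, radixin, from 12.3 to 15.2, LMNA from 2.66 to 3.08 and TMSB4X from 3.46 to 4.02. MSN, moesin, fell from 23.5 to 15.6, ARPC5 from 159 to 107, TUBB from 153 to 107 and ACTN1 from 28.2 to 20.2. ACTB was at 86.6 and 85.3 as deposited (adjusted p = 0.88) and rose after quantile normalization (log2 change 0.27, adjusted p = 0.0083). The median and mean of the list were below 0 (-0.05 and -0.10) while camera pointed up (adjusted p = 0.56). After quantile normalization the median was 0.18 and the camera adjusted p = 0.0496, against adjusted p = 0.39 with an estimated correlation there.

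Of 21 glycolysis and hypoxia genes 13 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.044, median log2 change -0.32). The call was lost with a correlation estimated for the list (adjusted p = 0.79 with an estimated correlation). PFKP, a phosphofructokinase, fell 1.82-fold from 13.7 ± 1.37 to 7.51 ± 0.254 (limma adjusted p = 8.9e-06), GPI fell from 30.4 to 20.2, HK1, a hexokinase, from 13.6 to 9.59 and PKM, pyruvate kinase, from 73.1 to 53.5. The median lay inside the range of random lists of the same level (percentile 4.66). After quantile normalization 5 were lower and the list did not pass (camera adjusted p = 0.18), nor did it without control array 3 (adjusted p = 0.085). Of 23 respiratory chain genes 15 fell and 0 rose, or 16 and 0 adjusted over the list alone (camera adjusted p = 0.019, median log2 change -0.26), but after quantile normalization 5 were higher and 3 lower and the median turned to 0.02 (camera adjusted p = 0.54). With a correlation estimated for the list the call was lost as well (adjusted p = 0.79 with an estimated correlation), and the deposited median lay inside the range of random lists of the same level (percentile 83.6). NDUFS1 fell from 38.5 to 25.4 under all scalings, UQCRC2 fell from 124 to 89.3 and ATP5F1B from 349 to 249, calls lost under cyclic loess (adjusted p = 0.062 and 0.132), and the fall of UQCRB (267 to 205) was lost after quantile normalization. With the stricter filter on dim probes, the heat shock (camera adjusted p = 0.080), membrane repair (0.276), glycolysis (0.276) and respiratory chain (0.300) lists did not pass.

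Of 24 cytosolic ribosomal protein genes 13 fell and 0 rose, or 14 and 1 adjusted over the list alone (camera adjusted p = 0.12, and 0.037 without exposed array 3), but after quantile normalization 1 was lower and 4, RPS23, RPL8, RPS9 and RPL3, higher, and the median turned from -0.21 to 0.06. The deposited median lay above the range of random lists of the same level (percentile 99.49), that is, less far below 0 than for other genes as bright; 12 of these genes lay near the top of the scale, at mean control levels of 563 to 636, with control array maxima of 755 to 811. Under cyclic loess the list stood higher than other genes (median 0.18, camera adjusted p = 8.7e-06), a call lost there with a correlation estimated for the list (adjusted p = 0.38 with an estimated correlation). RPL4 fell from 579 to 410, a call kept after quantile normalization and lost under cyclic loess (adjusted p = 0.31). The falls of RPLP2 (633 to 520), RPL32 (618 to 498) and RPS16 (598 to 495) were lost after quantile normalization and without the filter on dim probes, and their log2 changes were above 0 under cyclic loess, between 0.10 and 0.14.

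Of 22 genes of T cell lineage 10 fell and 1, BCL11B, rose, or 11 and 1 adjusted over the list alone, but after quantile normalization 4 were lower and 3 higher and the median turned from -0.17 to 0.04 (camera adjusted p = 0.33 and 0.50). LCK, a kinase of T cell receptor signalling, fell from 123 to 79.2, FYN from 91.4 to 62.6, LCP2 from 12.3 to 8.79 and CD28 from 32.5 to 24.0. Of 9 B cell markers 2 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.44, pointing up against a median of -0.01 and a mean of -0.02): CR2, from 1.95 to 1.52, and IGLL1, from 51.8 to 44.3. The IGLL1 call was lost without control array 2 (adjusted p = 0.067) or exposed array 2 (0.088), and its direction turned after quantile normalization (log2 change 0.05), where the list's median was 0.05 too. Of 6 myeloid and erythroid markers 0 passed, also adjusted over the list alone (camera adjusted p = 0.23), with CD68 at 1.67 and 1.86 and ALAS2 at 0.608 and 0.700. Of 6 epithelial and fibroblast markers 2 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.81): SPARC, from 5.80 to 4.45, and KRT18, from 0.582 to 0.354, a call lost on leaving out any of the 6 arrays (adjusted p between 0.052 and 0.120). Of 8 housekeeping genes 5 fell and 0 rose, also adjusted over the list alone, but after quantile normalization 2 were lower and 2, HPRT1 and ACTB, higher and the median turned from -0.22 to 0.04 (camera adjusted p = 0.29 and 0.65). TBP fell from 27.1 to 19.2 and GUSB from 5.38 to 3.95 under both scalings, whereas the fall of GAPDH (669 to 580) turned to a log2 change of 0.06 after quantile normalization (adjusted p = 0.37).

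**Figure D2:**
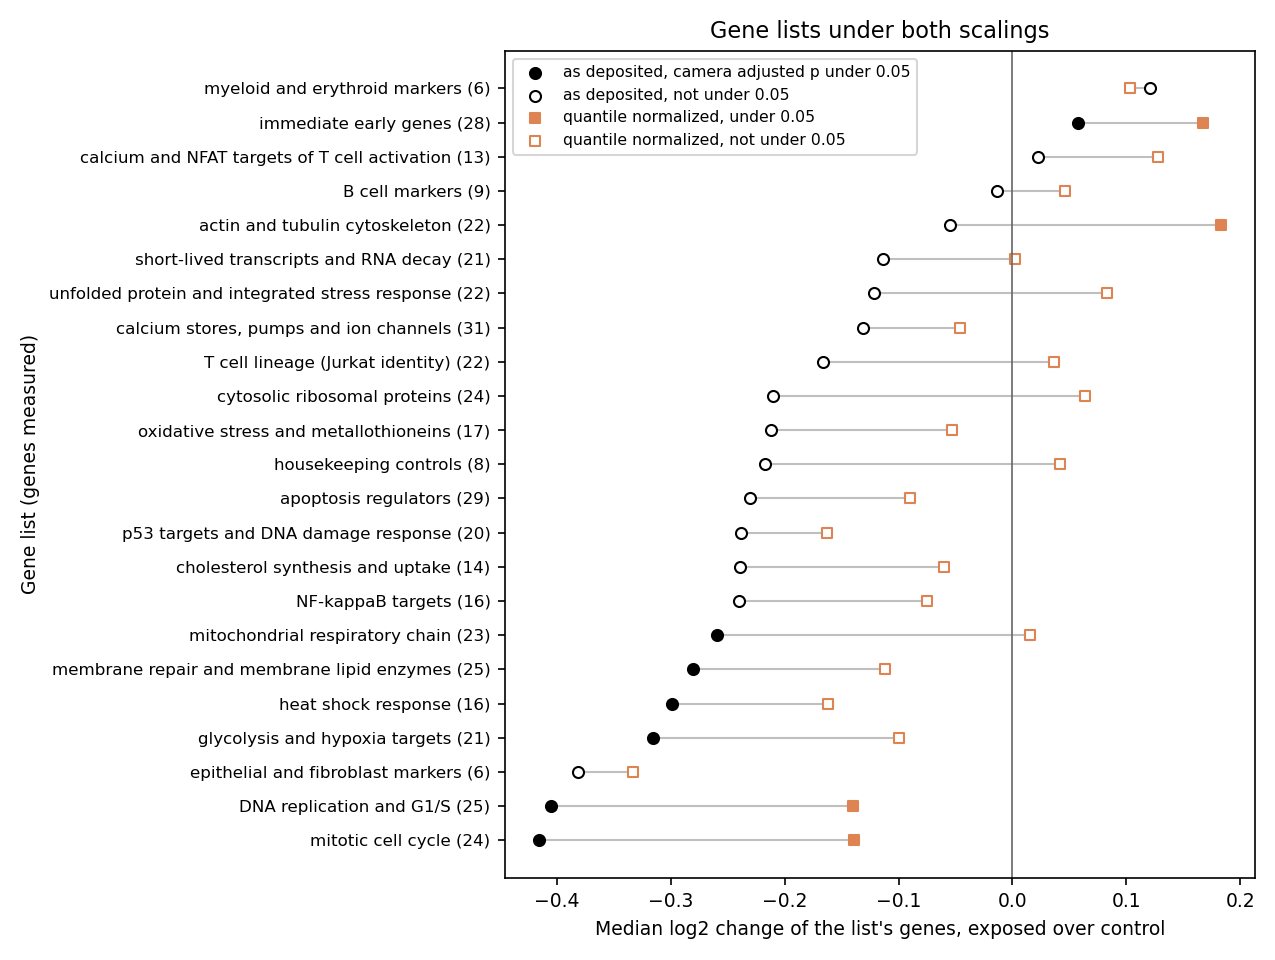
Median log2 change (exposed over control) of the genes of each of the 23 lists, with the number of genes measured in brackets; circles show deposited values, squares quantile-normalized values, and filled symbols a camera adjusted p under 0.05 at the preset correlation. As deposited 20 medians lie below 0, and 8 of them lie above 0 after quantile normalization, among them those of the ribosomal, respiratory chain, T cell and housekeeping lists.

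Against random lists of the same level, the deposited medians of 6 of the 23 lists lay outside the 95% range. The immediate early (percentile 99.08), cytoskeleton (100) and ribosomal (99.49) lists lay above it, and the mitotic (0.13), replication (0.2) and epithelial and fibroblast (0.94) lists below it.

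Of the 100 genes that the rule named, 25 had more than 1 tested probe. For GPI and GADD45B another probe passed in the opposite direction (log2 changes 0.23 and 0.38), and for GPI a further probe passed in the same direction (-0.45). For 15 genes no other probe passed: TGFBR1, TNFRSF10B, RCAN1, IDI1, TUBB, LCP2, VPS4B, ACTN1, HMGCS1, DNAJA1, CD28, UQCRB, GSR, SPARC and SOD2. KLF4, FAS, FYN, NFATC1, HK1, PFKP, SLC30A1 and XBP1 each had another probe that passed in the same direction, though not always by a similar amount. The log2 change of the other probe was 0.49 against 1.08 for KLF4, and -1.45 against -0.55 for FYN. A further probe did not pass for FYN (-0.21, limma adjusted p = 0.11) and for XBP1 (-0.30, limma adjusted p = 0.053).

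Over all 36365 probes, limma called 12466, 3161 higher and 9305 lower in exposed arrays (25.4% higher), and after quantile normalization 11077, 5298 higher and 5779 lower (47.8% higher). In both fits 8779 probes were called, all in the same direction. The groups did not overlap at 46.0% of probes, against 10% by chance for 3 against 3. Of the calls, 46 were at least 2-fold higher and 176 at least 2-fold lower; leaving out control array 2 gave 93 higher, control array 3 gave 141, and exposed array 2 gave 29. The pseudocount gave 4 and 70, the stricter filter 1 and 53, and no filter 126 and 276. The count of 3161 fell to 1603 without exposed array 2 and to 2064 without exposed array 3. Of the 176 probes, 155 were among the 18566 tested probes without a single gene. The balance of higher and lower calls followed the level of the probe. The median log2 change was 0.11 in the dimmest 10% and -0.28 in the brightest 10% of probes, where 93.7% were lower, and after quantile normalization it was 0.07 and -0.004. Over the 14500 genes the median log2 change was -0.13 as deposited and -0.02 after quantile normalization. This shift depends on the level, so a gene or list is to be read against others of the same level.

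**Figure D3:**
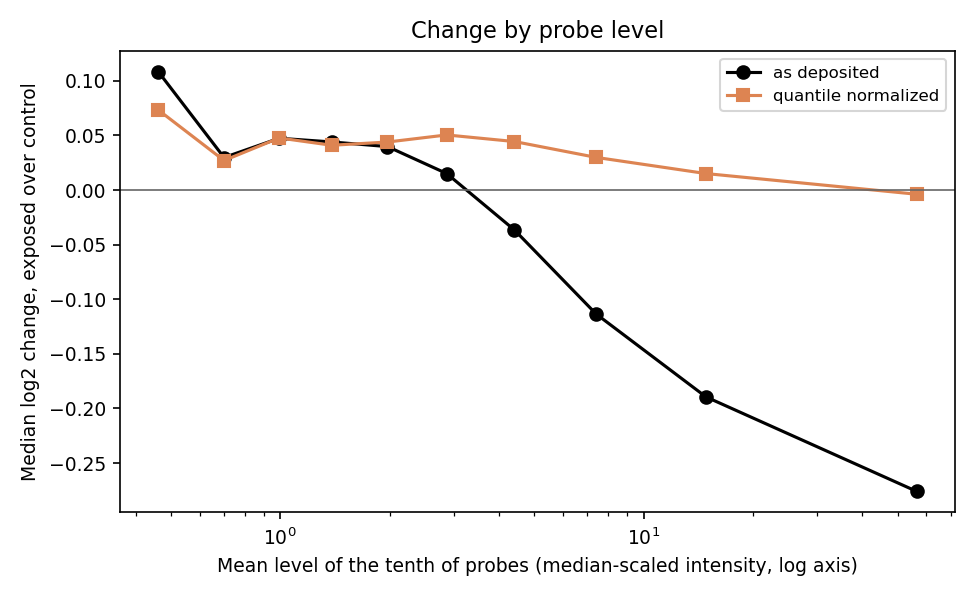
Median log2 change (exposed over control) of the 36365 tested probes in steps of 10%, ordered by mean level (median-scaled intensity, log axis), for deposited values (circles) and quantile-normalized values (squares). Deposited values fall from 0.11 in the dimmest to -0.28 in the brightest 10%, where the quantile-normalized median is -0.004.

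The comparison at 60 min and the comparisons between the times give no result here, since the columns labelled 60 min carry no measurement of their own.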

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

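Cyclic loess, the columns labelled 60 min, the mean of both column sets and all 12 columns as if separate were chosen after seeing the data; the other alternatives were planned. The result was 12466 called probes, 3161 higher and 9305 lower, 46 and 176 of them at least 2-fold, and 7 gene lists. Leaving out each array gave 8452 to 14650 calls, 1603 to 3731 higher, 6849 to 10919 lower, 29 to 141 at least 2-fold higher, 155 to 231 at least 2-fold lower and 5 to 8 lists; the ends past 1.5 times came without exposed array 2 (1603 higher and 29 at least 2-fold higher) or 3 (2064 higher) and without control array 2 (93 at least 2-fold higher) or 3 (141). Quantile normalization gave 5298 higher, 5779 lower and 4 lists, and cyclic loess 4980 higher and 5949 lower. The pseudocount gave 4 probes at least 2-fold higher and 70 lower, which follows from its construction, since it shrinks changes at low levels. No filter gave 1870 higher, and 126 and 276 at least 2-fold; leaving out the lowest 66.7% of probes gave 1512 higher, 1 and 53 at least 2-fold, and 3 lists, with fewer dim probes tested. Array weights gave 19051 calls, 6360 higher and 175 at least 2-fold higher. A correlation estimated per list left 0 lists, and fry called 18. The columns labelled 60 min gave 22 probes at least 2-fold higher, and all 12 columns 20447 calls, 7355 higher, by counting each array again. Apart from these constructions the cause was not tested. With the replicate number as a block 10521 probes were called, and the calls of IGLL1 (adjusted p = 0.054) and KRT18 (0.068) were lost; deviations of same-number arrays gave no sign of pairing (r across probes -0.098, -0.0075 and -0.098). For a list, direction is that of the test and the value its median. The direction was up by camera and down by fry for the unfolded protein (-0.121, fry adjusted p = 0.037), calcium and NFAT (0.0222), cytoskeleton (-0.0548), short-lived (-0.114) and B cell (-0.0132) lists. The last 4 passed neither test. Camera compares a list with the other genes and fry with no change, so no value turned between them. Directions reversed under quantile normalization for IGLL1 (log2 change 0.046) and the ribosomal (0.0638), respiratory chain (0.0155), T cell (0.0361) and housekeeping (0.0413) lists, where 8 of 20 list medians below 0 turned above it. Under cyclic loess they reversed for IGLL1 (0.0397), SOD1 (0.099), RPLP2 (0.128), RPL32 (0.104), RPS16 (0.136) and the ribosomal (0.176), respiratory chain (0.0726), T cell (0.0327), housekeeping (0.101) and oxidative stress (-0.0424) lists. The epithelial list reversed with no filter (-0.171) and without control array 3 (-0.398, in a range of medians over arrays of -0.474 to -0.265). Over the same fits the sign of the median turned for the calcium and NFAT (-0.018 to 0.038) and B cell (-0.059 to 0.054) lists. Medians kept their sign but moved for the unfolded protein (-0.193 to -0.068), cytoskeleton (-0.107 to -0.033), short-lived (-0.129 to -0.071) and immediate early (0.054 to 0.093) lists. Over all alternatives but leaving out an array, single genes kept direction and side of the threshold in 1226 comparisons, with 34 weaker, 8 stronger and 6 reversed. On leaving out an array they did so in 573, with 27 weaker. Lists did so in 276, with 17 weaker, 12 stronger and 15 reversed, 5 of these under fry. On leaving out an array they did so in 130, with 6 weaker, 1 stronger and 1 reversed. The counts of 1226 and 276 hold settings that nearly repeat the main values and could hardly differ. These were median scaling (100 genes and 23 lists the same), the columns labelled 60 min and the mean of both column sets (99 and 23 each). All 12 columns as if separate were another (99 genes the same). Fitting only the groups compared is the fit used, and a block across times equals the block; both were not run apart, nor was any alternative for the 60 min, time and agreement comparisons. Signal over background may limit the dim probes and was not measured here. The 4902 to 6595 probes per array at the floor follow largely from its definition as the percentile 10 of positive values.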

Other observations

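The gene families given first and all tests of explanations were chosen after the results were seen, except both tests of gene length. The bounds of those tests were written beforehand, but the lists they were run on had stood out in these data. The median of each of 15 families was set against 1000 random lists of the same level. Families were taken by the start of the gene symbol, so that some hold pseudogenes, antisense RNAs or genes of another function. Of 46 genes with DDX or DHX symbols, mostly RNA helicases, 35 fell and 2 rose (median log2 change -0.43, camera adjusted p = 9.1e-06, percentile 0 of random lists), and after quantile normalization 27 were lower and 5 higher (adjusted p = 0.00017); the calls were lost with an estimated correlation (adjusted p = 0.28 with an estimated correlation, and 0.097 after quantile normalization). DDX24 fell from 12.9 to 6.87, DHX30 from 50.4 to 30.2 and DDX50 from 106 to 68.5. Of 30 splicing factor genes 22 fell and 0 rose (camera adjusted p = 0.00040, and adjusted p = 0.41 with an estimated correlation), with 14 lower and 3 higher after quantile normalization, but the median lay inside the range of random lists (percentile 6.1). PRPF8, a core component of the spliceosome, fell from 26.4 ± 1.28 to 13.2 ± 0.265 (limma adjusted p = 6.9e-07) and SF3B3 from 7.68 to 4.28. Of 9 chaperonin genes 6 fell, among them TCP1 (251 to 172) and CCT4 (210 to 148), with 4 lower after quantile normalization (camera adjusted p = 0.0037, adjusted p = 0.26 with an estimated correlation, percentile 0.5). Of 356 zinc finger genes 166 fell and 17 rose, and after quantile normalization 140 and 29 (camera adjusted p = 0.048, adjusted p = 0.54 with an estimated correlation, percentile 0); ZNF700 fell from 20.6 to 10.9 and ZNF24 rose from 5.09 to 9.60. Of 33 kinesin genes 14 fell and 1 rose, and of 45 genes with USP symbols, mostly deubiquitinases, 23 fell and 3 rose (camera adjusted p = 0.24 and 0.11, percentiles 5.7 and 0.2). After quantile normalization these were 11 and 2, and 16 and 3 (camera adjusted p = 0.077 and 0.023; adjusted p = 0.22 with an estimated correlation for each).

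Of 52 genes with EIF symbols, which hold initiation factors and their regulators such as the kinases EIF2AK1 and EIF2AK4, 33 fell and 1 rose, of 37 proteasome genes 22 and 1, and of 74 mitochondrial ribosomal protein genes 47 and 0, but after quantile normalization the counts of lower and higher genes were 14 and 6, 2 and 6, and 5 and 11 (camera adjusted p = 0.0047, 0.051 and 0.00053 as deposited, and 0.98, 0.12 and 0.18 after quantile normalization). Both deposited calls, of the EIF genes and the mitochondrial ribosomal proteins, were lost with an estimated correlation (adjusted p = 0.52 with an estimated correlation for each, and 0.54 for the proteasome), and the medians lay at the percentiles 79.8, 98 and 97.6 for EIF genes, proteasome and mitochondrial ribosomal proteins. EIF4G2 fell from 37.2 to 19.7 and EIF3C from 99.7 to 58.6 under both scalings. Interleukin, noncoding RNA, olfactory receptor, KRT and KLF symbols held more rises than falls. Their mean levels were low, at 2.46, 1.95, 1.75, 1.98 and 4.01 in this order. Whether such signals come from the named genes was not tested. Of 57 interleukin and interleukin receptor genes 9 rose and 4 fell, and 16 and 4 after quantile normalization (camera adjusted p = 0.00029, adjusted p = 0.15 with an estimated correlation, percentile 99.9). IL12A, a subunit of interleukin 12, rose from 2.06 to 3.64 and IL7R, the interleukin 7 receptor, from 4.44 to 5.84, and IL16 fell from 4.41 to 2.83. Of 416 long intergenic noncoding RNA genes 65 rose and 24 fell, and 94 and 14 after quantile normalization. Camera's adjusted p was 1.6e-11, against 0.0036 with an estimated correlation and 0.086 with one after quantile normalization (percentile 100). Of 86 olfactory receptor genes 12 rose and 2 fell, of 51 genes with KRT symbols, among them KRTCAP3 and the pseudogene KRT8P12, 8 and 4, and of 16 genes with KLF symbols, among them the antisense RNA KLF3-AS1, 2 and 1 (camera adjusted p = 3.2e-08, 0.00040 and 0.021; adjusted p = 0.049, 0.049 and 0.15 with an estimated correlation; percentiles 100, 99.6 and 98). After quantile normalization 14 olfactory receptor genes were higher and 1 lower, with 11 and 3 for KRT and 5 and 0 for KLF symbols. With an estimated correlation there, the olfactory receptor and KRT calls by camera were lost (adjusted p = 0.14 and 0.20 with an estimated correlation). Of 38 histone genes 3 rose and 5 fell, among them H3-3B and H2AZ1 (log2 changes -0.28 and -0.25), but after quantile normalization 6 were higher and 0 lower (log2 changes -0.01 and 0.02); camera pointed up in both (adjusted p = 0.00071 as deposited, adjusted p = 0.076 with an estimated correlation, percentile 99.1). Of the 176 probes at least 2-fold lower, 155 had no single gene, where 24.5 were expected from single-gene probes of the same level. Among these 155, the smallest p by limma were those of probes 125022 and 55031. Probe 125022 fell from 8.65 ± 0.315 to 2.30 ± 0.163 (log2 change -1.91, limma adjusted p = 7.6e-09), and probe 55031 from 5.59 to 1.93 (log2 change -1.53).

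Abundant probes were lower in the exposed arrays, by a log2 difference of -0.277 between group means in the brightest 10% of probes. A scale of the arrays that depends on intensity may account for this, and so may a loss of abundant transcripts after exposure. Control arrays differed among themselves by up to 0.154 in these probes and exposed arrays by up to 0.059, while the smallest gap between a control and an exposed array was 0.165. Of the 4 lists taken as abundant for this test, chosen by hand, the ribosomal list lay above the range of random lists of the same level (percentile 99.49) and the T cell (97.33), respiratory chain (83.6) and housekeeping (83.7) lists inside it, while the replication list (0.2), brighter than the T cell list, lay below it. No array separates an effect of the array from that of the group, so both explanations cannot be told apart.

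The cell cycle lists were lower than the rest. A scale that depends on intensity would lower random genes of the same level as much. The medians of the mitotic and replication lists, -0.42 and -0.40, lay at or below the percentile 0.2 of 10000 lists of such genes. Both lay at or below the percentile 0.22 of lists matched on level and gene span. These percentiles treat genes as independent, while members of the lists varied together in the deposited values used for them (estimated correlations 0.35 and 0.33). After quantile normalization the estimated correlations were 0.016 and 0.024, but the percentiles were not computed there. The percentiles of the deposited medians therefore cannot decide on such a scale or on gene length. A biological response of cell cycle transcripts may underlie the pattern, as a hypothesis found and tested on the same data, with adjusted p = 0.79 with an estimated correlation. A difference between the cultures in growth before exposure was not tested.

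The immediate early list stood higher than the rest, with 10 of 28 members higher, though its call was lost with an estimated correlation (adjusted p = 0.79 with an estimated correlation, and 0.39 after quantile normalization). Random lists of the same level held 2 such members at the median and 9 at most (percentile 100). Their genes were drawn independently, while the members varied together as deposited (estimated correlation 0.10), so this count alone does not decide on a scale that depends on intensity. Quantile normalization and cyclic loess both even out such a scale. In each, 13 members were higher and 5 lower, with estimated correlations of -0.003 and 0.0005. These counts argue against such a scale as the account of those rises. Camera with an estimated correlation passed in neither (adjusted p = 0.39 and 0.38). Among the 11 brighter members 4 were higher and 4 lower, against a median of 0 in random lists (percentile 99.96). The rises were thus not confined to dim members, though this percentile has the same limit. Gene length stays open: the list's median lay at the percentile 96.66 of lists matched on level and span, inside their range, and its members go both ways. A response of immediate early genes to the exposure, or to handling that went with it, may underlie the pattern and was not tested further.

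The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05: the real split called 12466 probes with limma, and the highest of the other splits 0. The other splits hold arrays of both groups on each side, so a difference between the groups, whatever its cause, adds to their spread. Their 0 calls therefore do not bear on the calls of the real split.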
